A study of Rattus norvegicus with 2 samples.

How the data were processed

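RNA of the whole hypothalamus was measured in 9-week-old rats of the Wistar Kyoto strain, a normotensive strain often used as the control of hypertensive rats. Per the labels, RNA of 5 males was pooled in equal amounts into 1 sample and RNA of 5 females into another, 100 ng from each rat, and 150 ng of each pool was amplified and labelled with the dye Cy3. Each pool was hybridised to 1 array, so each group held 1 array and no replicate array. The arrays were Agilent 1-colour arrays for rat transcripts, with 44254 spots, of which 42877 were not controls. These carried 30367 different probes, most of them on 1 spot and a smaller set on 10 spots spread over the slide. Both arrays lay on the same slide and came from the same scan, per the file headers, so slide and scan did not separate the pools.

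The deposited scanner files gave an intensity for every spot. Per the file headers, the processed intensity of each spot was its signal after background subtraction and correction of a spatial trend, made by Agilent Feature Extraction 10.7.3.1, and the headers named the rat genome build rn4. The submitters' processing notes named Feature Extraction 9.1, and which of these versions made the values was not settled. The deposited value table held a signal that was, by comparison with the scanner files, the processed intensity divided by the 75th percentile of its array and multiplied by 100, on a linear scale without centring of genes. Its medians were 29.0 in the male pool and 29.5 in the female pool, it held 36348 spots matched by feature number, and the ratio to the scanner value was constant within each array. A 1-colour array has no ratio whose direction could be unknown. The deposited files also held other per-spot values, namely flags for spots well above background, saturated spots and outliers, set by Feature Extraction per the file headers.

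The 75th percentile of the processed intensity was 3769 in the male pool and 2943 in the female pool. A share of 84.9% of the non-control spots was well above background in the male pool and 84.2% in the female pool, and 0 spots were saturated. The median coefficient of variation of repeated spots, as the file headers gave it, was 4.15% in the male pool and 3.84% in the female pool.

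The level of a spot was log2 of the processed intensity minus the 75th percentile of that quantity over the non-control spots of its array. Spots flagged as outliers on either array were left out, 286 of the non-control spots on the male array and 292 on the female array carrying such a flag. Levels were averaged over the spots of a probe, and a probe was measured where over 50% of its spots were well above background on both arrays. Gene values were averages over the measured probes of the gene. Where a gene was well above background in 1 pool only, the difference was a bound, taken against the higher of the lowest level well above background on the dim array and the dim probe's own level. Differences were female minus male, and counts were made at 2-fold.

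Probes were named through their RefSeq accessions, with versions removed, in a gene table of the rat assembly GRCr8, of which only the names were used. This matched 19793 of the 30367 probes, a symbol, synonym or description matched 2590 more, and 7984 kept the name in the files. Together they stood for 26082 genes or other targets. Coordinates are those of the probes in the deposited files, build rn4.

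With 1 array per group no test was possible, and no p-value is given. Of 35 gene lists, the median difference was set beside 10000 random lists of the same size drawn from genes of like mean level in 20 bins, as a description of these 2 arrays. A list was said to stand apart where its median lay outside the central 95% of the random medians. About 1.75 of 35 lists would do so by chance if their genes varied independently. Genes of 1 list that vary together would raise that number. Technical error came from the repeated spots, as the spread of the difference between spots of 1 probe at a similar level, divided by the square root of the number of spots. Ranges of list medians over their members came from 10000 bootstrap draws. The technical error covers the scatter between spots of 1 probe within this slide, after flagged outlier spots were left out. It leaves out differences between the 2 hybridisations that all spots of a probe share, and labelling, pooling and the rats.

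The genes named were, by a rule set before the data were examined, the 15 largest differences per direction among genes with a settled symbol, the 5 largest bounds per direction among genes measured in 1 pool only, all measured members of the Y-linked list and of the list of X inactivation and escape genes, and the 4 largest differences of every other list, of which a few are not given here. Genes named outside this rule are said to be chosen after their values were seen. On simulated data for 20476 genes, with technical error as in the repeated spots, the calculation recovered 50 of 50 genes set at -2 log2, 44 of 44 genes set at -1.5 log2, 54 of 54 at 1.5 log2 and 52 of 52 at 2 log2, and called 0 of 20276 unchanged genes. All set differences lay well past the 2-fold limit, and the only error simulated was that of repeated spots. The simulation therefore checks the calculation and gives no rate of false calls in these data.

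Alternatives set beforehand were normexp background correction with an offset of 50, quantile and loess normalization, the median of detected probes, the deposited value table, no filter and a stricter filter on dim probes, the brightest probe per gene, outlier spots kept, and other thresholds. Normexp was fitted without the spots whose local background was flagged as non-uniform, 25 on the male array and 11 on the female array. With all spots included, the fitted background mean of the male array was -594.6 against 0.622 on the female array, because of spots as low as -19745 after subtraction, so leaving these spots out was decided after the fit on all spots was seen. That fit gave 9 genes at least 2-fold higher in the female pool and 7739 in the male pool, with a median of all genes of -0.55 log2, and the meningeal list stayed at percentile 100 of random lists. Alternatives added after the data were seen were leaving out bands of slide rows, using only probes spotted 10 times, and scaling by the spike-in probes. The bands were blocks of 20 rows in which over 1.5% of repeated spots lay beyond 4 robust SD of their own probe median, and these limits were chosen after the data were seen. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, were used.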

Results

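Gene expression was compared between the hypothalamus of male and female Wistar Kyoto rats aged 9 weeks, with 1 array of a pool of 5 males and 1 array of a pool of 5 females. The hypothalamus governs reproduction, feeding, water balance and the autonomic control of blood pressure, and the study asked how the sexes differ in brain regions of cardiovascular control. Of the 26082 genes and other targets on the arrays, 20476 were well above background in both pools, 320 in the female pool only and 516 in the male pool only. Every difference below is female minus male and has no replicate check, since each sex was measured on 1 array. An error given with a value is the SD over repeated spots of a probe, or for a gene with few spots the technical SD of genes of like level. It leaves out the spread between rats, between labelling reactions and between hybridisations.

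The hypothalamus of the 2 pools was alike for nearly all genes, and the gene groups that stood apart most were markers of the meninges and of blood. Genes of meningeal cells and fibroblasts were higher in the female pool, among them the small leucine-rich protein gene Ogn, 2.46-fold, and the collagen genes Col1a2 and Col3a1, 2.05-fold and 2.01-fold, the last 2 chosen after their values were seen. Of 13 blood cell markers 11 were lower in the female pool, among them Alas2 and Ahsp, by 1.40-fold and 1.49-fold. Among hypothalamic signals, the reproductive neuropeptide genes Kiss1 and Gnrh1 were 1.22 and 0.58 log2 higher in the female pool, Kiss1 from 1 spot in a part of the slide with frequent defects. The pituitary marker Tshb, which encodes the beta subunit of thyroid-stimulating hormone, was 4.15-fold higher in the male pool. All 18 measured genes of the renin-angiotensin system differed by less than 1.5-fold.

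At least a 2-fold difference was found for 104 genes higher in the female pool and 67 higher in the male pool, together 0.835% of the genes measured in both pools. Of these, 96 and 66 rested on a single spot. The SD of the difference over all genes was 0.23 log2, its robust SD 0.14, and 97.6% of genes lay within 1.5-fold. The repeated spots of 1 probe spread with an SD of 0.090 log2 around their probe median, 0.15 in the dimmest of 4 signal groups and 0.053 in the brightest. Spots that departed from their own probe median by over 4 robust SD crowded into bands of slide rows, from row 80 to 179, from 400 to 459 and from 520 to 532, where 4.77% of repeated spots did so against 0.384% elsewhere. The last of these bands held 0 single spots at least 2-fold apart. Genes with a measured spot in the bands made up 76 of the 104 and 63 of the 67, and without the bands, a setting chosen after the data were seen, 30 genes were at least 2-fold higher in the female pool and 5 in the male pool. A gene marked (band) below was measured on 1 spot inside these bands. The technical SD pools repeated spots of all slide rows and can understate the error of a spot inside a band. It was taken after spots flagged as outliers had been left out. It can therefore also understate the error of a single spot outside the bands.

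**Figure D1:**
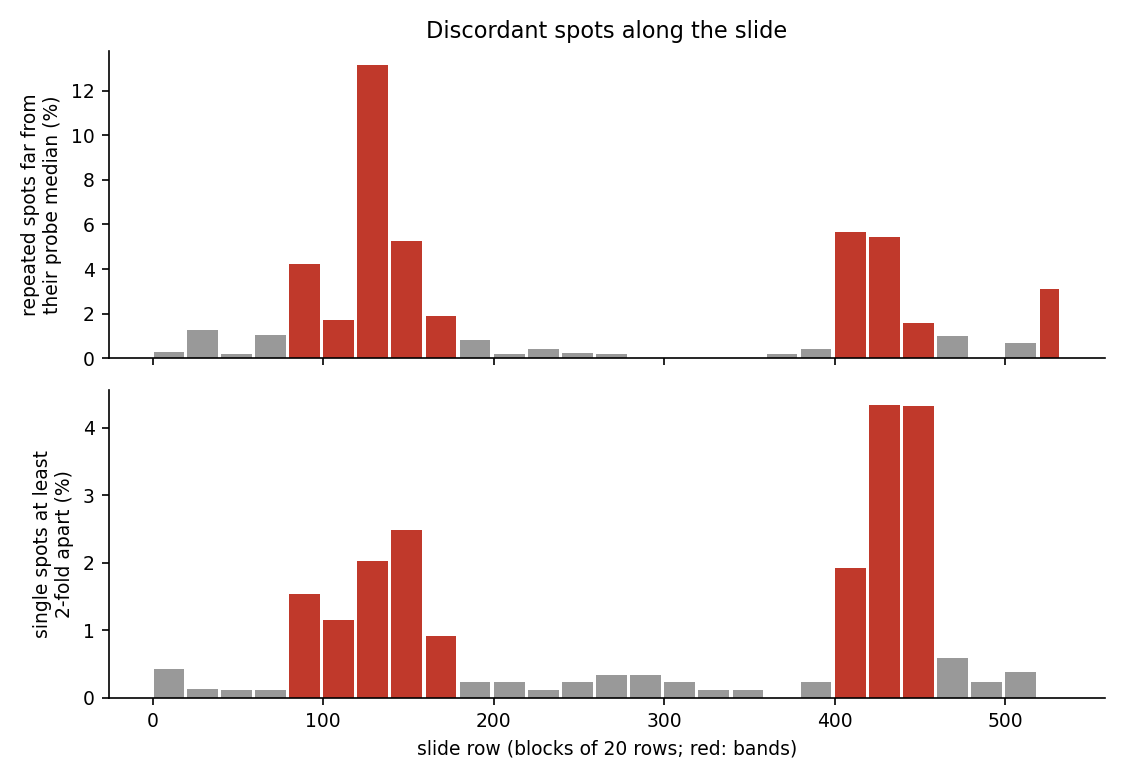
Percent of repeated spots that departed from the median of their own probe by over 4 robust SD (upper panel) and percent of probes on 1 spot that were at least 2-fold apart between the pools (lower panel), in blocks of 20 slide rows. Red bars are the bands defined from the upper panel, in which 2.20% of single spots were at least 2-fold apart against 0.230% outside.

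**Figure D2:**
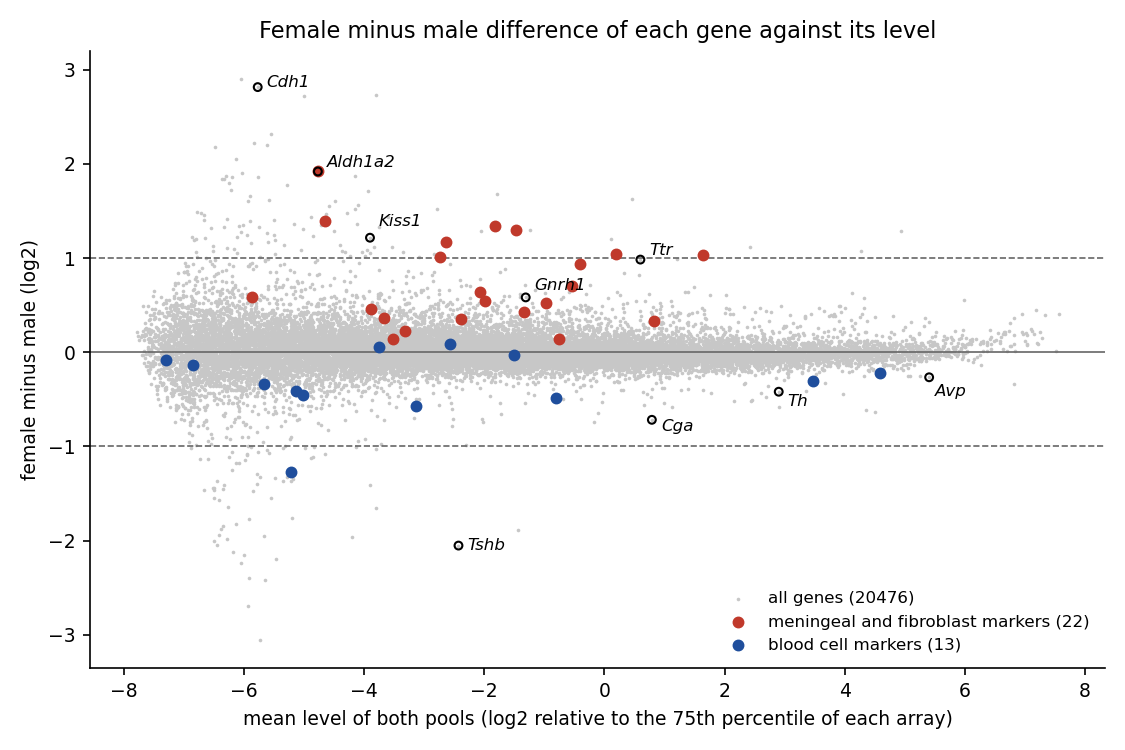
Female minus male difference (log2) of each gene measured in both pools against its mean level (log2 relative to the 75th percentile of each array), 1 point per gene and 1 array per pool. Dashed lines mark 2-fold; red points are the 22 measured meningeal and fibroblast markers, with a median of 0.61, blue points the 13 blood cell markers, with a median of -0.31, and open circles are other genes named in the text.

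The sex of the pools was checked on genes of the sex chromosomes. Ube1y1, a Y-linked relative of the ubiquitin-activating enzyme gene Uba1, was chosen after its value was seen and measured on 1 spot. It was well above background in the male pool and not in the female pool, at least 4.11-fold higher in the male pool. Sry, the testis-determining gene and the only listed Y-linked gene measured, gave the same level in both pools, a difference of 0.012 log2, so its spot did not tell the sexes apart. Tspy1, also listed, was not well above background in either pool. The probe of Ddx3, which the deposited annotation names Ddx3y but places on an autosome, was not counted as Y-linked. It was well above background in both pools, 0.24 log2 higher in the female pool. Of the Y-linked genes named here, only the 1 spot of Ube1y1 therefore told the sexes apart. That is weak evidence, since 121 genes had a bound of at least 2-fold in the male pool only. Whether the Ube1y1 spot lay inside a band is not given here. Xist, in the list of X inactivation and escape genes, was not measured. All 9 measured genes of that list were higher in the female pool, with a median of 0.078 log2 inside the central 95% of random lists, -0.099 to 0.088. The largest were the histone demethylase gene Kdm6a, 1.63-fold, the translation initiation factor gene Eif2s3, 1.44-fold with probes of 0.51 and 0.53 log2, and Pbdc1 (band), 1.34-fold. Kdm5c (band) and Ogt were each 1.06-fold higher, and Uba1 was 1.03-fold higher but lower, at -0.029, with spike-in scaling. The probes of Ddx3x gave -0.013 and 0.35 log2, and those of Usp9x and Zfx also differed in sign, with gene means of 0.026 and 0.040 log2 that turned to -0.040 and -0.026 with spike-in scaling. Over the 778 measured genes of chromosome X the median was 0.011 log2, within random lists, and -0.055 with spike-in scaling. The list stood above random lists in 4 of 12 alternatives, quantile normalization among them although its median there was -0.0043. Mbnl3, Lpar4, Rbmx and Magea13 had its largest differences among genes with a settled symbol, 3.05-fold, 2.50-fold, 2.29-fold and 1.99-fold higher in the female pool, the last 3 from spots inside the bands.

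The 15 largest differences higher in the female pool ran from 1.68 to 2.82 log2, and all rested on 1 spot. Those from spots outside the bands were Cdh1, which encodes the epithelial adhesion molecule E-cadherin, 7.04-fold (level -7.18 in the male and -4.36 in the female pool, technical SD 0.15), Mpzl2, another adhesion molecule gene, 4.13-fold, Mroh5, 3.73-fold, the signalling gene Wnt6, 3.64-fold, and the stress-induced gene Nupr1, 3.19-fold. The other 10 had their spot inside a band, namely Tsc1, 6.64-fold, Cfap91, 6.60-fold, Or9s15, 4.99-fold, the choroid plexus potassium channel gene Kcnj13, 4.67-fold, Ttll6, 4.58-fold, Aldh1a2, 3.78-fold, the macrophage receptor gene Marco, 3.46-fold, the sulfate transporter gene Slc26a2, 3.42-fold, Rnf19b, 3.30-fold, and Zbbx, 3.28-fold. The Cdh1 probe lies on chromosome 19 at 36511853 to 36511912, and the Aldh1a2 probe on chromosome 8 at 75771061 to 75771120.

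The 15 largest differences higher in the male pool ran from -1.55 to -2.70 log2, again from 1 spot each. Outside the bands lay Tshb and C1qtnf7, a gene of the complement C1q and tumour necrosis factor-related family, 4.15-fold and 4.71-fold higher in the male pool. Tshb was at -1.40 in the male and -3.45 in the female pool with a technical SD of 0.069, and its probe lies on chromosome 2 at 197908322 to 197908381. Inside the bands lay the other 13, Ndufaf2 with 6.48-fold, the guanylate-binding protein gene Gbp4 with 5.27-fold, the paraoxonase gene Pon3 with 4.60-fold, Ms4a5 with 4.12-fold, the odorant receptor gene Or9s14b with levels of -5.49 in the male and -7.50 in the female pool, Fev, a transcription factor gene of serotonin neurons, with 3.95-fold, Baat with 3.89-fold, Olr952 with 3.85-fold, the serotonin transporter gene Slc6a4 with 3.68-fold, Mup5 with 3.53-fold, Prr11 with 3.41-fold, Mucl3 with 3.12-fold and Hoxa2 with 2.92-fold.

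Of the genes well above background in 1 pool only, 115 in the female pool and 121 in the male pool had a bound of at least 2-fold. The largest bounds in the female pool were those of Art1, at least 80.2-fold, Sycp3l2, at least 21.5-fold, Espnl, at least 10.8-fold, Tgif2lx2, at least 10.7-fold, and Cd209el1, at least 9.57-fold, all with a spot inside a band. In the male pool they were those of Ly49i5, at least 16.9-fold, the taste receptor gene Tas2r121, at least 12.2-fold, the vomeronasal receptor gene Vom2r28, at least 11.3-fold, the odorant receptor gene Olr1481, at least 9.58-fold, and Mrgprx1, at least 9.56-fold. Of these, Olr1481 lay outside the bands.

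Meningeal and fibroblast markers were the group furthest from random lists. Of the 35 lists, 6 stood above and 2 below random lists, and this is a description of these 2 arrays. About 1.75 of 35 lists would do so if their genes varied independently, and more where genes of a list vary together. All 22 measured members were higher in the female pool, 11 of them by at least 1.5-fold and 8 by at least 2-fold, with a median of 0.61 log2 against -0.060 to 0.072 for the central 95% of random lists. The largest were Aldh1a2, 3.78-fold, the transporter genes Slc47a1, 2.63-fold, and Slc22a6, 2.54-fold, and Ogn, 2.46-fold, and the first 3 of these had their spot inside a band. Without the bands the median of the 16 remaining members was 0.50 log2. Among probes spotted 10 times, those of some genes were picked because they were higher in the female pool, and so are no test of the list: the fibroblast proteoglycan gene Dcn differed by 0.64 ± 0.043 log2 (SD, 8 spots), the meningeal transcription factor gene Foxc1 by 0.70 ± 0.071 (10 spots), the gap junction gene Gjb2 by 0.59 ± 0.069 (10 spots) and the homeobox gene Prrx2 by 1.47 ± 0.14 (9 spots).

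Blood cell markers lay on the other side. Of 13 measured members 11 were lower in the female pool, with a median of -0.31 log2 against -0.085 to 0.12 for random lists. The neutrophil genes S100a8 and S100a9 were 2.41-fold and 1.37-fold higher in the male pool, the former from a spot inside a band. Ahsp, which encodes a chaperone of alpha haemoglobin, was 1.49-fold higher, with probes of -0.58 and -0.56 log2, and Alas2, the erythroid enzyme of haem synthesis, 1.40-fold. The median was -0.083 with normexp and -0.20 when the brightest probe stood for each gene.

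Of 18 choroid plexus markers 12 were higher in the female pool, with a median of 0.14 log2 against -0.078 to 0.10 for random lists. Kcnj13 and the transthyretin gene Ttr were 4.67-fold and 1.98-fold higher, both from spots inside the bands, and Igfbp2 and Cdkn1c 1.52-fold and 1.51-fold. Without the bands the median of the 12 remaining members was 0.10 log2, within random lists. Myelin and oligodendrocyte markers had a median of -0.094 log2 against -0.058 to 0.032, with 20 of 26 lower in the female pool. Nkx6-2, Cntn2 and Cldn11 were 1.30-fold, 1.17-fold and 1.16-fold higher in the male pool, Gjb1 (band) differed by -0.26 log2, and no member reached 1.5-fold.

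Other cell types differed little, with medians that lay within random lists and were all below 0 with spike-in scaling. Astrocyte markers had a median of 0.026 log2, with Slc4a4 and Sox9 1.27-fold and 1.22-fold higher in the female pool and Hes5 1.21-fold higher in the male pool, while Gfap differed by -0.26 log2. Microglia and macrophage markers had a median of 0.011 log2, with the lysosomal gene Cd68 0.59 log2, the fractalkine receptor gene Cx3cr1 1.37-fold, Ptprc 1.27-fold and Cd163 1.24-fold higher in the female pool, although the Ptprc probe with 10 spots gave 0.024 log2 and its other probe 0.66 from 1 spot. Endothelial and mural cell markers had a median of -0.034 log2, with Cnn1 (band), Abcc9 (band) and Des 1.44-fold, 1.41-fold and 1.25-fold higher in the female pool and Notch3 (band) 1.39-fold higher in the male pool. Ependymal and tanycyte markers had a median of 0.018 log2, with Col25a1 1.46-fold, Vim 1.18-fold and the thyroid hormone-activating enzyme gene Dio2 (band) 1.16-fold higher in the female pool and Rax (band) 1.24-fold higher in the male pool.

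**Figure D3:**
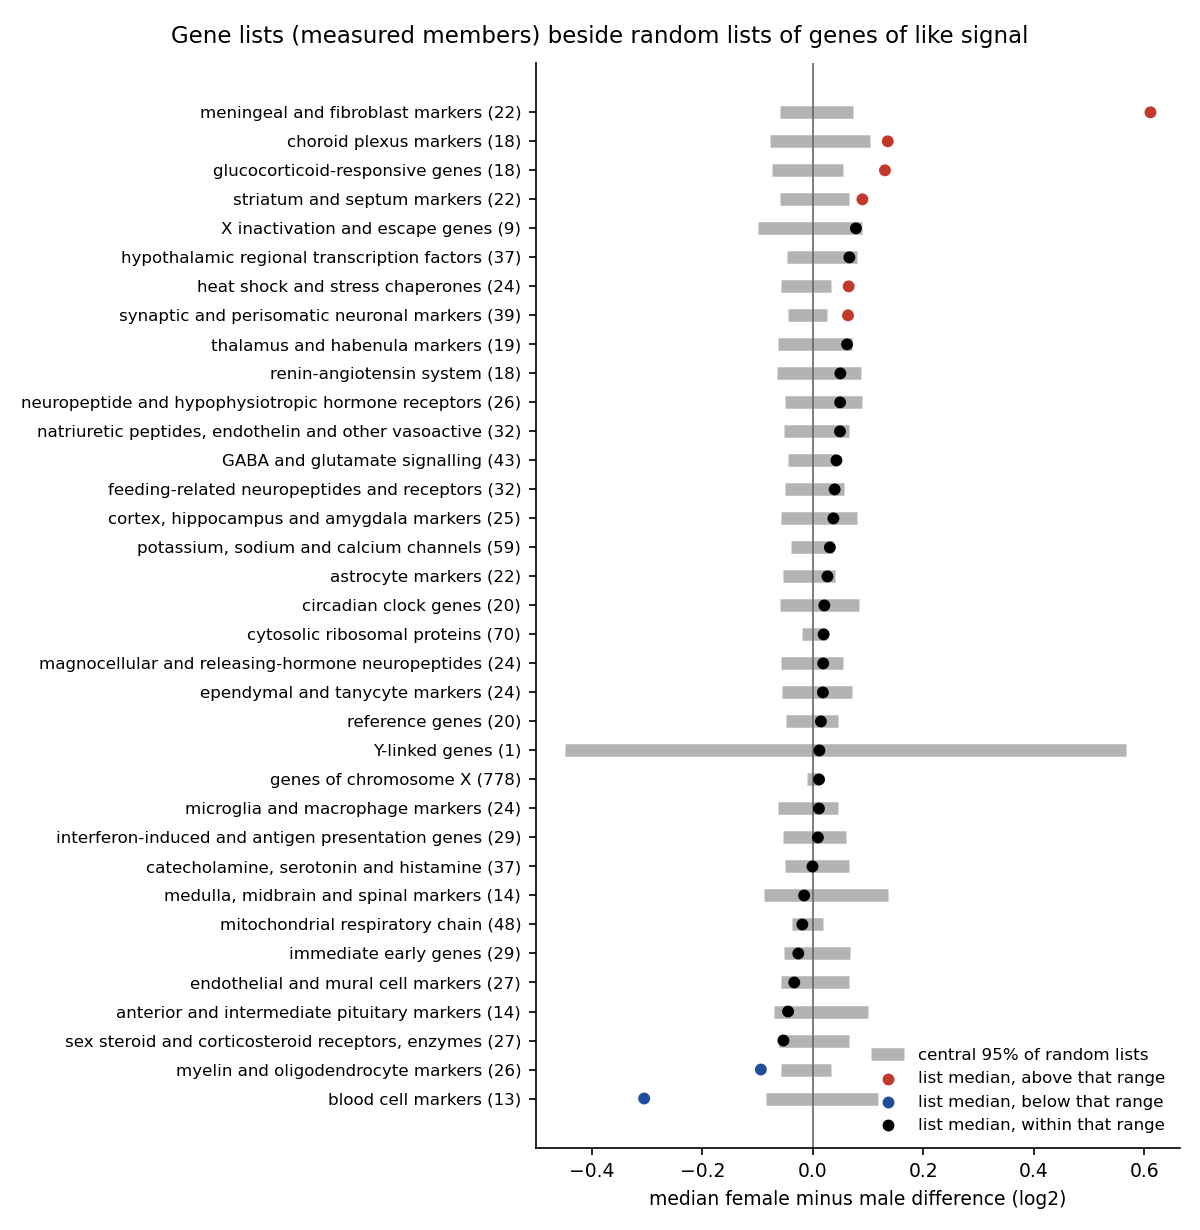
Median female minus male difference (log2) of each of the 35 gene lists (points, measured members in parentheses) beside the central 95% of the medians of 10000 random lists of genes of like level (grey bars). The meningeal list lies at 0.61 and the blood list at -0.31, and 27 lists lie within their grey bar.

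Among 24 measured magnocellular and releasing-hormone neuropeptide genes, 13 were higher and 11 lower in the female pool, with a median of 0.019 log2 within random lists and -0.047 with spike-in scaling. Kiss1, which encodes kisspeptin, the main excitatory input of gonadotropin-releasing hormone neurons, was at -4.51 in the male and -3.29 in the female pool, from 1 spot inside a band. The technical SD at its level, over all slide rows, was 0.11, which can understate the error inside a band. The Kiss1 probe lies on chromosome 13 at 46244823 to 46244882. Gnrh1, which encodes gonadotropin-releasing hormone, differed by 0.58 ± 0.029 log2 (SD, 9 spots). Crh, which encodes corticotropin-releasing hormone, was 1.33-fold higher in the female pool, with 0.45 ± 0.051 log2 over the 10 spots of its repeated probe. Th, the rate-limiting enzyme of dopamine synthesis, was 1.34-fold higher in the male pool from a spot inside a band. Avp, which encodes vasopressin and was chosen after its value was seen, was lower in the female pool, with a difference of -0.27 ± 0.029 log2 over 10 spots.

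**Figure D4:**
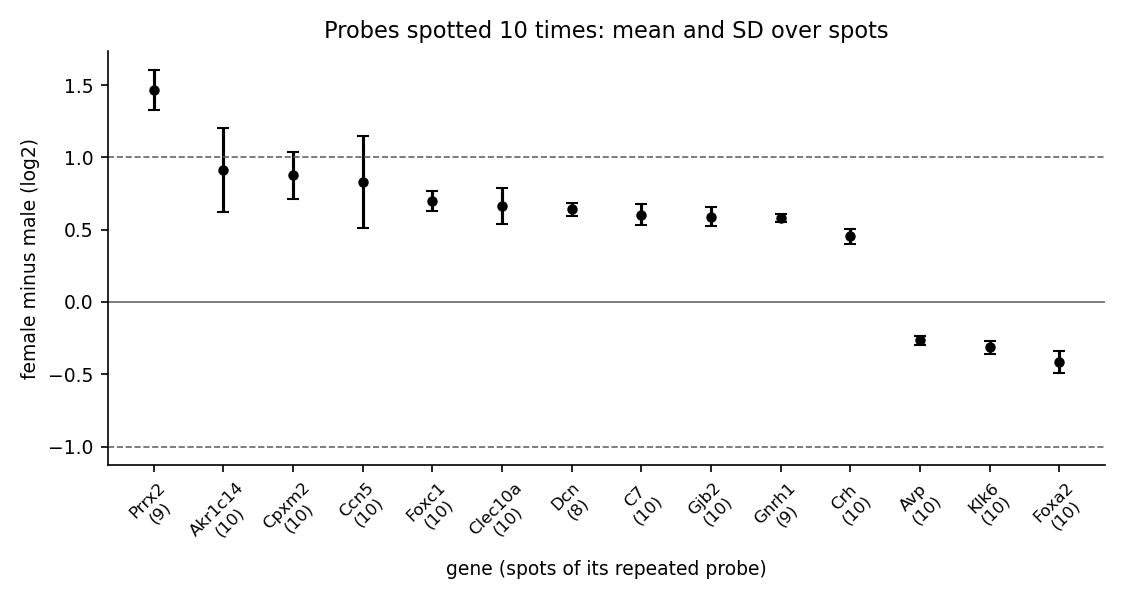
Female minus male difference (log2) for probes spotted 10 times, as mean and SD over the spots kept (number in parentheses), a technical error within 1 array per pool. Genes were chosen after their values were seen; Prrx2, at 1.47, was the only one of 1312 such probes at least 2-fold apart.

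Feeding-related neuropeptides and receptors had a median of 0.039 log2, with 21 of 32 higher in the female pool, and -0.026 with spike-in scaling. The receptor gene of thyrotropin-releasing hormone, Trhr (band), was 1.73-fold and the galanin receptor gene Galr1 1.25-fold higher in the female pool, and Qrfp and the appetite-stimulating peptide gene Agrp (band) were 1.49-fold and 1.23-fold higher in the male pool. Neuropeptide and hypophysiotropic hormone receptors had a median of 0.049 log2. The neurokinin B receptor gene Tacr3, the relaxin receptor genes Rxfp1 and Rxfp3 and the prolactin receptor gene Prlr were 1.32-fold, 1.26-fold, 1.23-fold and 1.21-fold higher in the female pool. Both lists lay within random lists, but the feeding list stood above them in 3 of 12 alternatives.

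Sex steroid and corticosteroid receptors and steroid enzymes had a median of -0.053 log2 within random lists, with 16 of 27 lower in the female pool. The largest differences went the other way: Akr1c14, a 3-alpha-hydroxysteroid dehydrogenase gene, was 1.88-fold higher in the female pool, with 0.91 ± 0.29 log2 over 10 spots, the steroid receptor coactivator gene Ncoa2 1.56-fold, the mineralocorticoid receptor gene Nr3c2 1.49-fold and the membrane estrogen receptor gene Gper1 (band) 1.22-fold. The spot of Ncoa2 lay inside a band. The progesterone receptor gene Pgr, chosen after its value was seen, differed by -0.25 log2.

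In the renin-angiotensin system, 13 of 18 measured genes were higher in the female pool with a median of 0.050 log2, which was -0.016 with spike-in scaling, and 0 reached 1.5-fold. The aminopeptidase gene Enpep (band), the kallikrein gene Klk1 and the aldosterone synthase gene Cyp11b2 were 1.24-fold, 1.16-fold and 1.10-fold higher in the female pool. Natriuretic peptide, endothelin, kinin, nitric oxide and other vasoactive factors had a median of 0.049 log2. Edn3, which encodes endothelin 3, was 1.54-fold higher in the female pool from a spot inside a band, the bradykinin receptor gene Bdkrb2 1.45-fold and Adm2 1.33-fold, while Uts2 (band) was 1.33-fold higher in the male pool. Catecholamine, serotonin and histamine genes had a median of -0.00068 log2. Besides Slc6a4, the dopamine transporter gene Slc6a3 was 1.45-fold higher in the male pool, with probes of -0.83 and -0.25 log2, and the receptor genes Htr1a (band) and Hrh1 (band) were each 1.35-fold higher in the female pool. All 3 lists lay within random lists.

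Synaptic and perisomatic neuronal markers had a median of 0.064 log2 against -0.046 to 0.026 for random lists, a shift that came to -0.0022 with spike-in scaling. Cplx2 and Pam were 1.62-fold and 1.53-fold higher in the female pool from spots inside the bands, and the synaptic adhesion gene Nlgn1 1.34-fold. GABA and glutamate signalling genes had a median of 0.043 log2, within random lists but above them in 7 of 12 alternatives and -0.023 with spike-in scaling, with Grin2a (band) 0.59 log2, Gabrg1 (band) 1.37-fold, Gabra4 1.30-fold and Gria4 1.29-fold higher in the female pool, although the Gria4 probe with 10 spots gave 0.0014 log2 and its other probe 0.73 from 1 spot. Potassium, sodium and calcium channels had a median of 0.031 log2, with Kcnk9 (band) 1.61-fold and Kcnb2 (band) 1.35-fold higher in the female pool and Kcnj11 (band) 1.29-fold higher in the male pool, and probes of Cacna1a that gave -1.21 and 0.38 log2.

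Glucocorticoid-responsive genes stood apart, with 12 of 18 higher in the female pool and a median of 0.13 log2 against -0.073 to 0.055. The transcription factor gene Zbtb16 was 2.21-fold higher from a spot inside a band, Sult1a1 1.40-fold, Tsc22d3 (band), which encodes the glucocorticoid-induced leucine zipper, 1.25-fold and the clock gene Per1 1.24-fold. Heat shock and stress chaperones had a median of 0.065 log2 against -0.059 to 0.033, which came to -0.00099 with spike-in scaling, with Hsp90b1 0.27 log2 and Hspa1b, Hsp90ab1 and Hspa1l 1.19-fold, 1.11-fold and 1.11-fold higher in the female pool. Immediate early genes had a median of -0.026 log2, with Egr3 and Fosl1 1.68-fold and 1.28-fold higher in the female pool and Ccn1 and Atf3 1.33-fold and 1.28-fold higher in the male pool. Circadian clock genes had a median of 0.021 log2, with Per2 1.17-fold higher in the female pool, Per3 1.10-fold higher in the male pool and probes of Csnk1e that differed in sign. Interferon-induced and antigen presentation genes had a median of 0.0091 log2, yet the class II genes RT1-Da, Cd74 and RT1-Bb were 1.91-fold, 1.58-fold and 1.28-fold higher in the female pool, and Bst2 1.25-fold. These last 3 lists lay within random lists.

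Markers of tissue next to the hypothalamus were read for the dissection. Anterior and intermediate pituitary markers had a median of -0.045 log2 within random lists, with 9 of 14 lower in the female pool. Besides Tshb, the common glycoprotein hormone subunit gene Cga was 1.64-fold higher in the male pool from a spot inside a band and the pituitary transcription factor gene Pou1f1 1.37-fold, while Fshb was 1.13-fold higher in the female pool. Prl, which encodes prolactin and was chosen after its value was seen, was well above background in the female pool only, at least 4.74-fold higher. Striatum and septum markers had a median of 0.090 log2 against -0.059 to 0.066, with Gpr101 1.35-fold, the dopamine receptor gene Drd1 (band) 1.32-fold and Foxp2 1.27-fold higher in the female pool, and the list lay within random lists without the bands, with a median of 0.046 over 16 members. Thalamus and habenula markers, with a median of 0.062 log2, included Tac3 (band) with 1.25-fold, Six3 (band) with 1.21-fold, Zic1 with 1.21-fold and Lef1 with 1.18-fold higher in the female pool. Cortex, hippocampus and amygdala markers had a median of 0.037 log2, with Ccn2 1.33-fold higher in the female pool and Slc17a7 1.21-fold higher in the male pool. Medulla, midbrain and spinal markers had a median of -0.016 log2, with Hoxd3 1.82-fold higher in the female pool and, besides Slc6a4 and Hoxa2, En1 1.62-fold higher in the male pool, all 4 from spots inside the bands. Hypothalamic regional transcription factors had a median of 0.066 log2 within random lists, with Six6 1.61-fold, Pou3f2 1.38-fold and Lhx8 (band) 1.34-fold higher in the female pool and Foxa1 (band) 1.54-fold higher in the male pool.

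Housekeeping groups set the scale of small differences. Mitochondrial respiratory chain genes had a median of -0.019 log2, with Uqcrq, Cox6c and Ndufa5 (band) 1.14-fold, 1.13-fold and 1.12-fold higher in the female pool. Cytosolic ribosomal protein genes had a median of 0.019 log2, with Rpl14, Rps9 (band), Rpl27 and Rplp0 1.17-fold, 1.14-fold, 1.11-fold and 1.10-fold higher in the female pool. Reference genes had a median of 0.015 log2, with Polr2a (band) and Ppib (band) 1.13-fold and 1.12-fold higher in the female pool and Eef1a1 (band) 1.08-fold higher in the male pool. These 3 medians lay within random lists, and with spike-in scaling they came to -0.085, -0.046 and -0.051 log2. Of the 10 spike-in probes, 7 were well above background on both arrays, and they differed by 0.066 ± 0.049 log2 (SD over probes), from -0.032 to 0.11.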

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

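The tests in this part were chosen after the results were seen, except the test of a second meningeal list, whose prediction was written before its values were looked at.

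Of 25 control probes that are neither spike-ins nor negative controls, 3 were well above background on every kept spot of both arrays. Their mean log2 processed intensities in the male and female pool were 5.45 and 5.30 for the probe named ERCC-00012_90, 5.57 and 5.30 for ERCC-00062_278, and 5.39 and 4.91 for ETG05_66023. The negative control spots had medians of 1.95 and 1.71, with single spots up to 7.73 and 5.81.

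Differences of at least 2-fold crowded into bands of slide rows, though not into the band from row 520 to 532, with 0 of 475 single spots. With bands found from part of the repeated probes, spots of the other repeated probes departed from their own probe median at least 9.47 times as often inside as outside, which is what local slide defects would give. Dim probes were not more common there, with a ratio of 1.01 for their share. A real difference of these genes as a set is argued against by the 25 of 163 such spots whose gene had another probe measured outside the bands. Those other probes differed in the same direction by a median of only 0.102 log2 (bootstrap 95% range -0.035 to 0.17) against 1.38 for the spots inside, although 1 of the 25 was again at least 2-fold apart. The spots inside were picked for their size. Any error of single spots, not only a defect in the bands, would therefore give a smaller second value. Of all 12713 kept repeated spots, however, only 1 lay at least 2-fold from its own probe median. Inside the bands, 163 of 7411 single spots were at least 2-fold apart between the pools. The kept repeated spots thus show frequent defects in the bands, but hardly any of 2-fold size. Local defects on this slide stay a candidate for much of the list of single-spot genes at least 2-fold apart, in particular those higher in the male pool. These values do not settle it.

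Meningeal and fibroblast markers were higher in the female pool. Local slide defects are argued against, since the list stayed above random lists without the bands, with a median of 0.498 log2. A lower share of neurons and glia is argued against as the whole cause, since it would raise other cells alike, while the largest median of the endothelial, choroid plexus and blood lists was 0.136 log2 (bootstrap 95% range -0.046 to 0.24, that of the choroid plexus) against 0.44 to 1.02 for the meningeal median; a part in it stays open, as the choroid plexus list stood above and the myelin list, at -0.094 log2, below random lists. A second list of 30 measured meningeal and perivascular fibroblast genes, none of them in another list and all well above background in both pools, had a median of 0.225 log2, above the -0.049 to 0.087 of random lists, as more meningeal tissue in the female pool would give. More meninges left on the dissected tissue of the females is thus a candidate explanation, and a sex difference of these genes themselves was not tested and stays open.

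Tshb and Cga were higher in the male pool. Pars distalis tissue in the male pool is argued against, since 0 of the 2 probes of Gh1 and Prl, abundant transcripts of that tissue, were well above background there. Against this, Lhb, Fshb and Pou1f1 were well above background in both pools, and Pou1f1 was 1.37-fold higher in the male pool from a spot outside the bands. A Gh1 probe that does not work was also not excluded. For local slide defects, 1 of the 2 spots, that of Tshb, lay outside the bands, so for Cga they cannot be told apart from a difference of the pools. Gh1 and Prl speak to the pars distalis only, so tissue from other parts of the pituitary was not tested and stays open. A sex difference in thyrotropin-producing cells was also not tested and may remain among the explanations.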

How the results depend on the processing

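Row bands, probes spotted 10 times and spike-in scaling were alternatives chosen after the data were seen. No paired analysis was possible because each group held 1 array, and leaving out replicates was not possible for the same reason. The meningeal list stood above random lists, and the blood list below, in all 11 alternatives that could be run for them, with medians from 0.50 to 0.62 and from -0.37 to -0.083 log2, and the glucocorticoid list stood above in its 11. Of 1626 values of the 163 named genes under the alternatives, 1611 kept their sign and 0 genes at least 2-fold apart changed it. Most named genes rest on 1 spot and most alternatives rescale the same spots, so a sign could hardly change. Leaving out the bands dropped genes whose only spot lay inside them and did not test them. Signal over background limits the counts: of the 171 genes at least 2-fold apart, 13 were found with the stricter filter, which kept the brighter probes. Where no reason is given, the cause was not tested.

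The counts of genes at least 2-fold higher in the female and male pool, 104 and 67, were 40 and 6 with normexp, which shrinks differences of dim spots. Normexp also moved the median of all genes to 0.050 log2, and put 87.0% of calls in the female pool against 60.8%. The 2 counts were 216 and 177 with no filter on dim probes, 12 and 1 with the stricter filter, 30 and 5 without the bands, and 1 and 0 with only probes spotted 10 times, which left 1304 genes. They were 319 and 173 at 1.5-fold, 27 and 23 at 3-fold, and 594 and 230 beyond 3 robust SD of genes of like level. Counts in 1 pool only, 115 and 121, were 27 and 12 with normexp, 26 and 17 without the bands, 0 and 0 with probes spotted 10 times, 224 and 205 at 1.5-fold and 62 and 60 at 3-fold. The SD over genes was 0.14 with the stricter filter and 0.13 with probes spotted 10 times. Normexp fitted on all spots gave 9 and 7739 genes and a median of all genes of -0.55 log2, and was not used further.

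With normexp, list medians moved to 0.11 (feeding), 0.094 (neuropeptide receptors), 0.012 (steroid), 0.10 (renin-angiotensin), 0.091 (vasoactive), 0.063 (catecholamine), 0.074 (GABA and glutamate), 0.019 (immediate early), 0.071 (interferon), 0.016 (pituitary), 0.24 (choroid plexus), 0.062 (endothelial), 0.58 (meningeal), -0.083 (blood), 0.14 (cortex), 0.055 (medulla), 0.11 (hypothalamic factors) and 0.064 (chromosome X). The median of all genes was 0.050 log2 with normexp, so part of the upward moves is a shift of all genes. The steroid, pituitary and medulla medians there lay at percentiles 10.9, 14.15 and 5.15 of random lists. With quantile normalization they were -0.029 (clock), 0.036 (synaptic), 0.0069 (ribosomal) and -0.0043 (chromosome X), and with the median of detected probes 0.044 (synaptic), -0.039 (mitochondrial), -2.1e-05 (ribosomal) and -0.0083 (chromosome X). Chromosome X was at 0.0046 with loess, and the pituitary list at 0.029 with no filter.

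The stricter filter gave -0.048 (neuropeptide receptors), -0.049 (clock), 0.081 (choroid plexus), -0.0086 (thalamus), 0.090 (cortex), 0.032 (striatum), 0.039 (synaptic) and -0.0038 (chromosome X). The brightest probe gave -0.022 (clock), -0.20 (blood) and -0.0013 (channels). Without the bands the medians were -0.020 (clock), -0.00095 (endothelial), 0.50 (meningeal), 0.046 (striatum), 0.037 (synaptic) and -0.011 (reference). With only probes spotted 10 times, where few members were left, they were 0.45 (releasing hormones), 0.097 (feeding), 0.18 (neuropeptide receptors), -0.021 (steroid), 0.0014 (GABA and glutamate), 0.013 (immediate early), 0.14 (heat shock), -0.039 (myelin), 0.034 (striatum), -0.030 (channels), -0.026 (synaptic, reversed), -0.037 (reference) and 0.031 (chromosome X). Spike-in scaling, which lowers every difference by 0.066, gave 0.065 (glucocorticoid), -0.00099 (heat shock, reversed), 0.070 (choroid plexus), -0.16 (myelin), 0.55 (meningeal), -0.37 (blood), 0.024 (striatum) and -0.0022 (synaptic, reversed). These are the 8 lists that stood apart, a limit set after nearly every list was seen to move by that constant, while percentiles among random lists hardly depend on it.

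Some lists within random lists stood above them in alternatives, namely GABA and glutamate in 7 of 12, chromosome X in 4, feeding in 3, channels in 2 and releasing hormones in 1, and of 11 X inactivation and cortex in 2 each and ribosomal and thalamus in 1 each. Of the lists that stood apart, choroid plexus and striatum lay within random lists in 3 of 12, which were the stricter filter, leaving out the bands and probes spotted 10 times, and heat shock, synaptic and myelin in 1, probes spotted 10 times.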

Other observations

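Several genes outside the fixed lists, chosen after their values were seen, were higher in the female pool together with the meningeal markers. The transcription factor gene Foxc2 was 2.56-fold higher, the growth factor gene Bmp7 2.57-fold, and Ptgds, which encodes a prostaglandin D synthase of the cerebrospinal fluid, 2.45-fold, each from a spot outside the bands. Of the probes spotted 10 times, Cpxm2 differed by 0.87 ± 0.16 log2, Ccn5 by 0.83 ± 0.32 and the lectin gene Clec10a of tissue macrophages by 0.66 ± 0.12, each over 10 spots.

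In the other direction, and also chosen after their values were seen, Foxa2 differed by -0.41 ± 0.078 log2 and the oligodendrocyte protease gene Klk6 by -0.31 ± 0.045, each over 10 spots. From 1 spot each, the growth hormone-releasing hormone gene Ghrh was 1.28-fold and the proopiomelanocortin gene Pomc 1.21-fold higher in the male pool, the latter inside a band of slide rows with frequent defects.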
